A study of Rattus norvegicus with 78 samples.

How the data were processed

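Expression in the dorsal part of the left hippocampus was measured in 78 rats of 8 groups, with 1 RAE230A array per animal. The deposited values are signal intensity on a linear scale, made by the authors with MAS5 in GCOS 1.1, per the submitters' processing notes. The deposited arrays had been scaled to a common mean intensity: the mean after trimming 2% at each end lay between 500.08 and 500.1 in every array. No further normalization was applied. Correlations of log2 signal between arrays ran from 0.8699 to 0.9882, and the number of arrays limits the precision.

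Each array held 15923 probe sets, of which 57 controls were left out. Of the others 12783 carried 1 gene symbol, 312 several and 2771 none. A probe set was tested when its signal was above the 40th percentile of its own array in at least 9 arrays, the size of the smallest group, which kept 10371 probe sets, 8695 of them with 1 symbol, from 7489 genes. Log2 of signal plus 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) as 8 group means, and 17 contrasts were taken from that fit. Benjamini-Hochberg adjusted p under 0.05 over the tested probe sets counted as passing. Standard errors are those of the fit. The 3 comparisons of aged with young rats, and the 2 of impaired with unimpaired rats, share no array with each other. No overlap or correlation is given between comparisons that share a group.

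Gene lists for cell types and pathways were written before the data were examined, as were the contrasts, the tests and the first set of alternatives. Of 32 lists 31 had at least 5 measured genes, that of blood cells having 3, and were tested with camera of limma, with 1 probe set per gene, the brightest. The preset correlation of 0.01 gave the calls, adjusted over the lists of a contrast, and a correlation estimated from the data was computed beside it. Not every called list is described, and the number called in each comparison is given with the random divisions. Members were counted as risen or fallen after adjustment over all probe sets and after adjustment over the list alone. Data were simulated by shuffling the residuals of the fit over all arrays. This did not keep the balance of scan days over the groups, so that the shares below may differ from those in the real design. With 200 changed probe sets, a change of log2 0.5 was recovered in 90.2% of cases in the untrained comparison. In impaired against unimpaired rats on day 5 it was recovered in 86%. A change of log2 0.25 was recovered in only 41.6% and 42.9%. Of the calls 10.5% and 3.4% were false. For a list shifted by log2 0.2, tested on simulated data in the same comparisons, the preset correlation recovered it in 10 of 10 runs each and called 7.1 and 2.8 other lists on average. The estimated correlation recovered it in 8 and 6 of 10 runs and called 0.1 and 0 others.

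Genes were named by a rule fixed in advance. For each contrast the rule took the 10 largest rises and 10 largest falls among probe sets with 1 symbol past the threshold, using the probe set with the smallest p of each gene, and up to 4 members with the smallest p of each list with a call or a counted member. Where fewer than 10 probe sets passed, the 10 genes with the smallest p were taken as values. For impaired against unimpaired rats Arc, Egr1, Fos, Homer1, Slc2a1, Mbp, Mobp, Gfap and C3 were added, and not every gene that the rule names for this comparison is reported. Probe sets with several symbols or none were not named.

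Scan day, chip lot and fluidics module came from the deposited array records and maze measures from the deposited animal table. Maze measures were compared between groups by exact permutation of the group labels, adjusted over 48 comparisons, and array quality by 100000 permutations of an F statistic. Alternatives changed 1 choice at a time: quantile normalization, a pseudocount of 32, no filter, replicate number as a block, the letter of the animal code, scan day as a block, the 3' over 5' ratio of Gapdh as a covariate, and only the arrays of the contrast. Fluidics module, the actin ratio, the removal of 5T-AI replicate 4 or 21PT-Y replicate 6 and, for gene lists, scan day and the letter were added after the data were seen. List tests were also run with the mean of a gene's probe sets. Groups were divided at random 100 times to ask how often chance gave as large a result, and again with arrays moved only within a scan day. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.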

Results

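RNA from the dorsal part of the left hippocampus was measured in 78 male F344 rats, with 1 Affymetrix RAE230A array per animal and 15923 probe sets per array. Young rats were 4 to 6 and aged rats 24 to 26 months old. Untrained rats formed the groups NT-Y (young, n = 10) and NT-A (aged, n = 10). Rats trained in the Morris water maze, in which a swimming animal learns the place of a hidden platform, were sampled on day 5, the last day of training, or 21 days after it. Aged trained rats were divided by the authors into unimpaired (AU) and impaired (AI). The trained groups were 5T-Y, 5T-AU and 5T-AI (n = 10 each) on day 5, and 21PT-Y (n = 9), 21PT-AU (n = 10) and 21PT-AI (n = 9) on day 21.

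The median signal per array lay between 229.2 and 269 intensity units and did not differ between the 8 groups (permutation p = 0.543), and the number of arrays limits the precision. The 3' over 5' ratio of the Gapdh control did not differ either (permutation p = 0.232), while that of beta-actin did (F = 2.39, permutation p = 0.0294), with means from log2 0.60 ± 0.23 (SD, n = 10) in 21PT-AU to 0.99 ± 0.38 (SD, n = 9) in 21PT-Y. One array, 5T-AI replicate 4, stood apart from the rest, with a mean correlation of 0.906 to the other arrays against a median of 0.971. Each of the 11 scan days held at most 1 array of a group, so that a difference within a day rested on single arrays without a spread, and scan day was fitted as a block instead. The 3 chip lots held 3 or 4 arrays of every group. The 4 fluidics modules nearly followed the groups, with all 10 NT-Y arrays in module 1 and 8 of the 10 NT-A arrays in module 4, so that differences within a module could be formed for few groups and module was fitted as a term. This term, the actin ratio as a covariate and the removal of 5T-AI replicate 4 were chosen after the data were seen. The first letter of the animal code also followed the groups in part, with 5 unimpaired and 0 impaired rats of letter L on day 5. Differences below are in log2 signal ± the standard error of the fit, with an adjusted p from limma, and counts of arrays are those on the shifted side of the mean of the group compared with. For RT1-Ba, RT1-Bb, RT1-Da, Fcgr2b, Glra2, Hspb1, Serping1, Flt1, Gpd1, Lgals3, Fos, Homer1, Klf9, Cacna1a, Htr7 and Adcy8 the dimmest group of at least 1 comparison had a mean under the filter level, the 40th percentile of the array. The sizes given for these depend on dim signal and carry no order.

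Maze performance set the groups apart by design. Times to the platform, path lengths and swim speeds were averages over the later training days. In the day 5 groups impaired rats needed 50.1 ± 8.05 s (SD, n = 10) to reach the platform. Unimpaired aged rats needed 16.2 ± 2.47 s (n = 10) and young rats 10.9 ± 5.52 s (n = 10). In the day 21 groups the times were 54.9 ± 14.2 s (SD, n = 9), 16.8 ± 1.77 s (n = 10) and 10.5 ± 4.20 s (n = 9). Impaired and unimpaired rats differed in both cohorts (2-sided exact permutation test, p = 1.08e-05 in each, adjusted p = 7.42e-05 over 48 comparisons), and their ranges did not overlap. In the probe trial impaired rats of the day 5 groups dwelt 1.65 s and unimpaired rats 4.68 s at the former platform site (exact permutation test, adjusted p = 0.000236). In the day 21 groups these times were 1.28 and 3.84 s (adjusted p = 0.00036). Swim speed was 22.9 cm/s in impaired and 23.1 cm/s in unimpaired rats of the day 5 groups (exact permutation test, adjusted p = 0.701). Unimpaired aged rats took longer to the platform than young rats in both cohorts (exact permutation test, adjusted p = 0.0278 in the day 5 and 0.00211 in the day 21 groups). Their paths were longer too (same test, adjusted p = 0.0488 and 0.00498). In the day 5 groups young rats also swam faster, at 26.0 cm/s, than unimpaired (adjusted p = 0.0488) and impaired rats (adjusted p = 0.0321). In the day 21 groups no such difference in speed passed (adjusted p = 0.59 and 0.201).

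**Figure D1:**
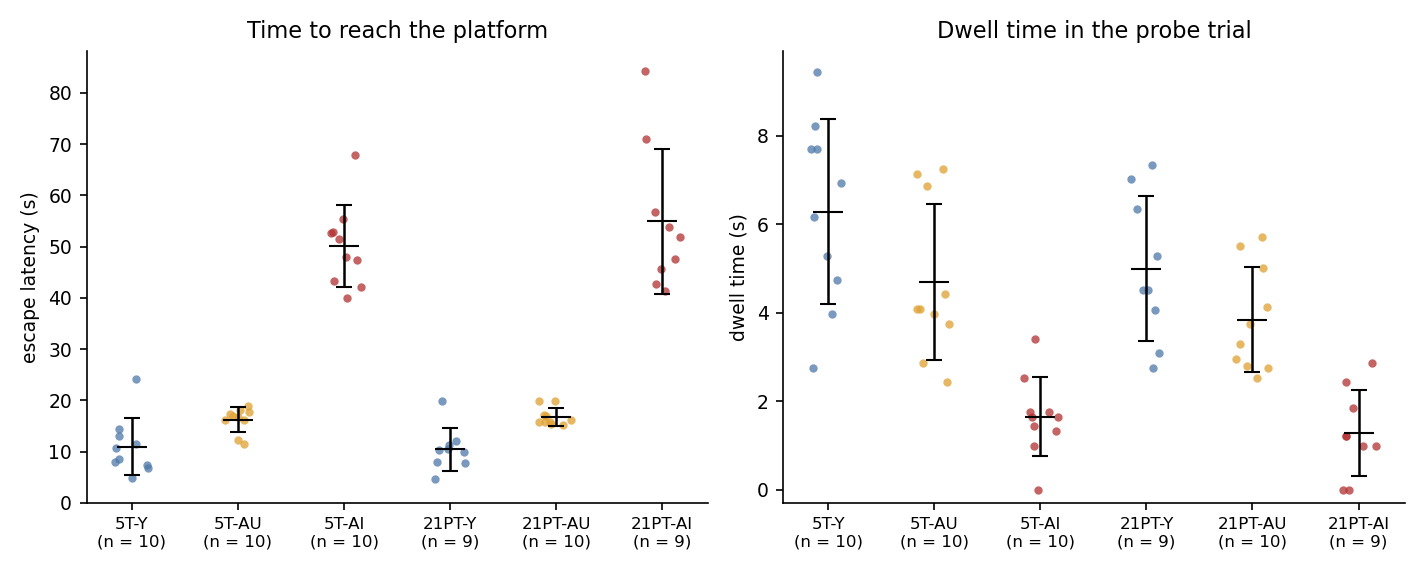
Escape latency in s (left) and probe trial dwell time in s (right) of the 6 trained groups, 1 point per rat, with bars for the mean and SD. Latencies were averaged over the later training days, with means in impaired rats of 50.1 s in the day 5 groups and 54.9 s in the day 21 groups.

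The comparison of untrained aged with untrained young rats asked what age alone changed. Large rises were those of the MHC class II chains RT1-Ba (2.55 ± 0.28, adjusted p = 2.08e-10), RT1-Bb (2.29 ± 0.24, adjusted p = 2.52e-11) and RT1-Da (2.02 ± 0.19, adjusted p = 3.53e-13). Each was higher in 10 of 10 aged arrays. In young rats these chains lay under the filter level, and with a pseudocount of 32 the rises were 1.98, 1.81 and 1.81. Cd74, the chaperone of class II molecules, rose by 1.70 ± 0.17 (10 of 10 arrays). C3, the central protein of the complement cascade, rose by 1.19 ± 0.12 (adjusted p = 8.08e-12, 10 of 10 arrays). Fcgr2b, an Fc receptor of microglia and macrophages, rose by 1.13 ± 0.19 and the lysosomal protease Ctss by 0.56 ± 0.10. The small heat shock protein Hspb1 rose by 1.21 ± 0.23 and the astrocyte filament protein Gfap by 0.25 ± 0.06 (adjusted p = 0.00509). Falls were fewer, among them Glra2, a glycine receptor subunit (-1.14 ± 0.29, adjusted p = 0.0249), Grp, a neuropeptide precursor (-0.77 ± 0.19, 9 of 10 arrays), and Tubb2b, a tubulin of growing neurons (-0.36 ± 0.08). Tfrc, the transferrin receptor, fell in 1 of its 2 probe sets (-0.27 ± 0.05).

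By gene list, 6 of the 21 measured antigen presentation genes rose over all probe sets and 7 adjusted over the list alone (median 0.21, adjusted p = 3.67e-20, and adjusted p = 0.000172 with an estimated correlation). Of the 7 complement genes, 2 rose over all, C3 and C1qa, and 6 adjusted over the list alone (median 0.47, adjusted p = 6.73e-14, and adjusted p = 0.00284 with an estimated correlation). Among 24 microglia markers 5 rose over all and 15 adjusted over the list alone, with a median of 0.32 (adjusted p = 1.01e-15, but adjusted p = 0.0869 with an estimated correlation). This became 2.55e-10 without 5T-AI replicate 4. Lysosome genes had a median of 0.14 with 2 of 32 risen over all and 4 adjusted over the list alone (adjusted p = 8.25e-09, but adjusted p = 0.174 with an estimated correlation). This became 1.51e-06 without that array. Of the oligodendrocyte and myelin genes 2 of 31 rose over all, Qdpr and Cryab, and 8 adjusted over the list alone (median 0.12, adjusted p = 2.66e-08, but adjusted p = 0.242 with an estimated correlation). Astrocyte markers (median 0.05, adjusted p = 0.174 with an estimated correlation) and ribosomal protein genes (0.05, adjusted p = 0.514 with an estimated correlation) passed with the preset correlation and not with the estimated one. Immediate early genes, which neurons switch on with activity, had a median of -0.10, with 0 fallen over all and 3 adjusted over the list alone (adjusted p = 0.000581, but adjusted p = 0.174 with an estimated correlation).

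In all, 81 of 10371 probe sets passed, 59 higher and 22 lower, from 65 genes. With scan day as a block 119 passed and with fluidics module as a term 27. Without 5T-AI replicate 4, a setting chosen after its correlation was seen, 170 passed. With the scan day block the medians were 0.21 for antigen presentation, 0.47 for complement and 0.32 for microglia. Within the 3 chip lots the complement shifts were 0.40, 0.36 and 0.54, the microglia shifts 0.25, 0.39 and 0.35, and the antigen presentation shifts 0.24, 0.10 and 0.24.

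The comparison of aged with young rats on day 5 asked the same question in a separate set of trained animals (n = 20 and 10). RT1-Da rose by 2.30 ± 0.16 and C3 by 1.46 ± 0.10 (both adjusted p = 1.67e-19), Cd74 by 1.84 ± 0.15 and Fcgr2b by 1.44 ± 0.17, each in 20 of 20 aged arrays. The complement starters C1qa (0.69 ± 0.11) and C1qb (0.75 ± 0.13) rose together with Serping1, the C1 inhibitor (2.14-fold, 20 of 20 arrays, adjusted p = 2.20e-05). Lysosomal Npc2, a cholesterol carrier, rose by 0.68 ± 0.08 and Lamp1 by 0.26 ± 0.06, and the filament genes Gfap by 0.28 ± 0.05 and Vim by 0.68 ± 0.15. Sgk1 (0.77 ± 0.15, 18 of 20 arrays) and Nfkbia (0.67 ± 0.17, 16 of 20 arrays), both induced by glucocorticoids, also rose. Sgk1 passed as higher with age in untrained rats (0.76) and on day 21 (0.56) too. Homer1, a synaptic scaffold with an activity-induced short form, fell in 1 of its 5 probe sets (-0.64 ± 0.10, adjusted p = 4.98e-06), and Trib2 (-0.35 ± 0.05) and Glra2 (-1.29 ± 0.25) fell in 20 of 20 arrays. One of the 2 Tfrc probe sets fell (-0.30 ± 0.04) and the other had the opposite sign.

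Of the lists on day 5, complement (6 of 7 risen over all, 7 adjusted over the list alone, median 0.69, adjusted p = 1.22e-22, adjusted p = 8.29e-05 with an estimated correlation) and microglia (12 of 24 and 17, median 0.36, adjusted p = 4.06e-23, adjusted p = 0.0145 with an estimated correlation) shifted up. Antigen presentation genes did so too (8 of 21 and 8, median 0.16, adjusted p = 1.16e-16, adjusted p = 0.000581 with an estimated correlation), as did lysosome genes (7 of 32 and 19, median 0.16, adjusted p = 1.31e-14, adjusted p = 0.0469 with an estimated correlation). Glucocorticoid-responsive genes had 4 of 22 risen over all and 6 adjusted over the list alone (median 0.14, adjusted p = 5.72e-06, but adjusted p = 0.0522 with an estimated correlation). Astrocyte (0.05, adjusted p = 0.0921 with an estimated correlation), myelin (0.06, adjusted p = 0.294 with an estimated correlation), interferon (0.16, adjusted p = 0.294 with an estimated correlation) and ribosomal genes (0.07, adjusted p = 0.294 with an estimated correlation) passed with the preset correlation alone. Calcium handling genes had a median of -0.06 (adjusted p = 0.00566, but adjusted p = 0.272 with an estimated correlation). For calcium handling the preset adjusted p was 0.0616 without 5T-AI replicate 4.

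For the day 5 cohorts 259 probe sets passed, 210 higher and 49 lower, from 216 genes. In other fits 379 passed with scan day as a block and 54 with fluidics module as a term. The blocked medians were 0.69 for complement, 0.36 for microglia, 0.16 for antigen presentation and 0.16 for lysosome genes (adjusted p = 0.0577 with an estimated correlation for the last). Within lots complement shifted by 0.57, 0.90 and 0.63, microglia by 0.34, 0.64 and 0.28 and antigen presentation by 0.14, 0.27 and 0.12.

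In the day 21 cohorts (19 aged, 9 young) the immune genes rose again, with RT1-Da (2.27 ± 0.17, adjusted p = 6.06e-18), RT1-Bb (2.27 ± 0.22), Cd74 (1.91 ± 0.16), C3 (1.14 ± 0.11) and Fcgr2b (1.33 ± 0.18) each higher in 19 of 19 aged arrays. Hspb1 rose by 1.83 ± 0.21 (adjusted p = 1.33e-09) and its relative Cryab by 0.73 ± 0.08. Gpd1, a glycerol phosphate dehydrogenase of oligodendrocytes, rose by 0.73 in the brighter of its 2 probe sets. The dimmer one passed as well (2.17 ± 0.37, and 1.42 with a pseudocount of 32), against a young mean of log2 5.21. Astrocyte genes rose as well, among them Gfap (0.25 ± 0.05), Vim (0.61 ± 0.15), Cst3 (0.21 ± 0.05) and Itih3 (0.28 ± 0.07). Of the vessel genes Cldn5, a tight junction protein (0.52 ± 0.14), Flt1, a receptor of vascular growth factor (0.54 ± 0.14), and Slc2a1, the glucose transporter of the blood-brain barrier (0.29 ± 0.07, 16 of 19 arrays), rose, while Tfrc fell in 1 of its 2 probe sets (-0.25) and had the opposite sign in the other. Rasgef1b (-0.54 ± 0.09, with its other probe set at -0.35), Glra2 (-1.25 ± 0.26) and Pcp4, a calmodulin-binding peptide (-0.28 ± 0.06), fell, each in 19 of 19 arrays by the first value given.

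On day 21 the list shifts were 0.66 for complement (6 of 7 risen over all and 7 adjusted over the list alone, adjusted p = 3.72e-18, adjusted p = 0.000354 with an estimated correlation) and 0.39 for microglia (11 of 24 and 18, adjusted p = 6.77e-22, adjusted p = 0.0143 with an estimated correlation). Antigen presentation (7 of 21 and 8, median 0.16, adjusted p = 7.73e-20, adjusted p = 0.00023 with an estimated correlation) and astrocyte genes (6 of 28 and 9, median 0.10, adjusted p = 7.65e-09, adjusted p = 0.0114 with an estimated correlation) passed with both correlations. Lysosome (0.12, adjusted p = 0.141 with an estimated correlation, 3.64e-06 without 5T-AI replicate 4) and vessel genes (4 risen and 1 fallen over all of 18, median 0.12, adjusted p = 0.391 with an estimated correlation) passed with the preset correlation alone. So did heat shock genes (2 of 38 risen, median 0.02, adjusted p = 0.141 with an estimated correlation), myelin genes (0.10, adjusted p = 0.386 with an estimated correlation) and, lower in aged rats, genes of oxidative phosphorylation (-0.04, adjusted p = 0.727 with an estimated correlation).

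Here 295 probe sets passed, 220 higher and 75 lower, from 230 genes. There were 487 with scan day as a block, 116 with fluidics module as a term and 164 with the actin ratio, which was highest in 21PT-Y, as a covariate. The blocked medians were 0.66 for complement, 0.39 for microglia, 0.15 for antigen presentation and 0.09 for astrocyte genes. Within lots complement shifted by 0.57, 0.74 and 0.53, microglia by 0.33, 0.52 and 0.46 and antigen presentation by 0.18, 0.14 and 0.22.

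**Figure D2:**
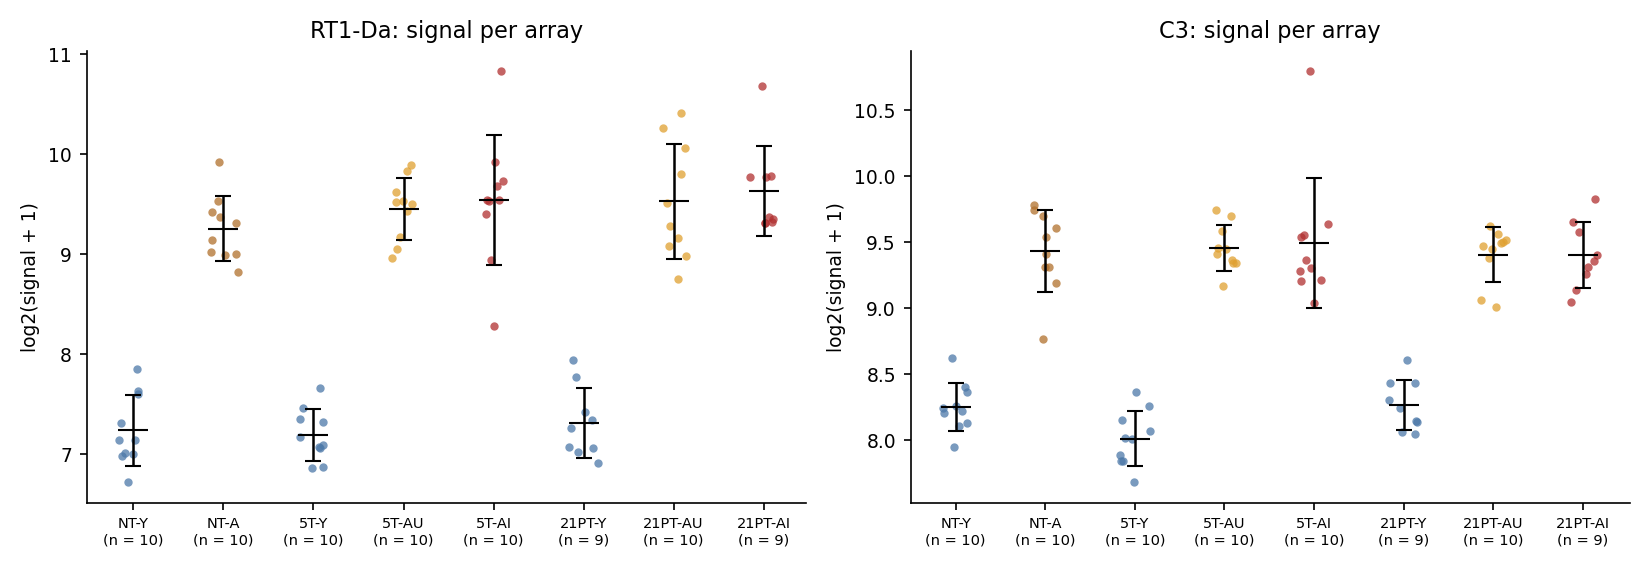
Log2 signal of RT1-Da (left) and C3 (right) in the 8 groups, 1 point per array, with bars for the mean and SD. For C3 the aged groups had means of 9.40 to 9.49 and the young groups of 8.01 to 8.27.

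The 3 comparisons of aged with young share no array, so that each can be set against the others. They come from the same fit, however, and share its residual variance for each probe set. The numbers below for independent lists leave this out. Of the 81 probe sets that passed in untrained rats, 79 had the same sign on day 5 and 81 on day 21. Past the threshold with the same sign were 65 on day 5 and 60 on day 21, where independent lists would share 1.19 higher and 0.104 lower, and 1.25 higher and 0.159 lower. In all 3 cohorts 56 passed, 45 higher and 11 lower, from 45 genes, and 0 passed with opposite signs. Averaged over cohorts Cd74 was at 1.81 and C3 at 1.26. RT1-Da (2.19), RT1-Bb (2.18) and RT1-Ba (2.04), dim in young rats, are not ranked. Hbb, a globin of red blood cells named here after its value was seen, was at 0.91 and passed in each cohort. Among the lower genes were Glra2 (-1.23) and Sema3c, a guidance protein of axons (-0.50). The shared number was 106 without 5T-AI replicate 4 and 15 with fluidics module as a term.

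**Figure D3:**
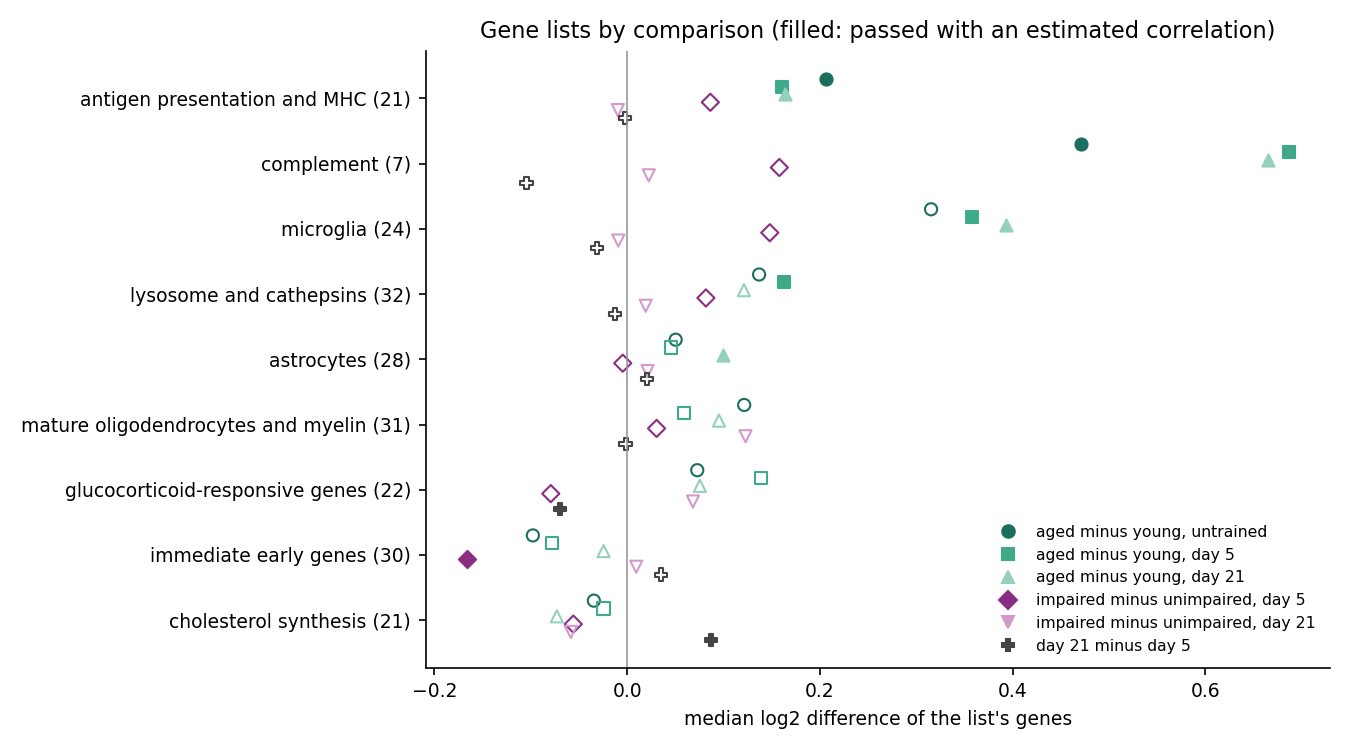
Median log2 difference of the genes of 9 lists (number of genes in parentheses) in 6 comparisons, 1 symbol per comparison, filled where the list passed with an estimated correlation. Complement shifted by 0.47, 0.69 and 0.66 with age in the 3 cohorts, and immediate early genes by -0.17 in impaired against unimpaired rats on day 5.

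Each aged performance group was also compared with young rats of its own day, to ask which changes of age accompanied spared and failed learning. Both comparisons of a day use the same young arrays, so that similar values in them are not independent. On day 5 unimpaired rats (n = 10) had higher RT1-Da (2.26 ± 0.19, adjusted p = 7.22e-16), C3 (1.45 ± 0.12) and Npc2 (0.64 ± 0.10), and lower Glra2 (-1.48 ± 0.29) and Homer1 (-0.71 ± 0.12, 1 of 5 probe sets with another of opposite sign, adjusted p = 2.09e-05), each in 10 of 10 arrays. The glucocorticoid-induced genes Sgk1 (0.94 ± 0.17) and Nfkbia (0.98 ± 0.20, 9 of 10 arrays) rose in them, and 3 of 22 genes of that list rose over all and 9 adjusted over the list alone (median 0.18, adjusted p = 4.91e-08, adjusted p = 0.0194 with an estimated correlation). The call with an estimated correlation ended with the letter of the animal code as a term. Impaired rats (n = 10) had RT1-Da higher by 2.35 ± 0.19 (adjusted p = 1.90e-16), C3 by 1.48 ± 0.12, Fcgr2b by 1.60 ± 0.19 and Lgals3, a galectin of activated microglia, by 1.14 ± 0.26. Their immediate early genes Arc (-0.47 ± 0.12, adjusted p = 0.012, 9 of 10 arrays) and Egr1 (-0.30 ± 0.08, adjusted p = 0.015, 10 of 10 arrays) fell, and so did 1 of the 5 Homer1 probe sets (-0.56 ± 0.12). In that list 2 of 30 genes fell over all and 6 adjusted over the list alone (median -0.10, adjusted p = 3.20e-05, but adjusted p = 0.0702 with an estimated correlation). Arc was also lower with age in untrained rats, without passing (-0.39 ± 0.12, adjusted p = 0.117 in limma). Unimpaired and young rats had mean log2 signals of 9.67 and 9.91 for Arc and 10.95 and 11.22 for Egr1 on day 21. On day 5 these means were 9.83 and 9.76 for Arc and 11.15 and 11.21 for Egr1. Complement had medians of 0.57 in unimpaired rats (5 of 7 over all and 7 adjusted over the list alone, adjusted p = 0.000528 with an estimated correlation) and 0.80 in impaired rats (6 and 7, adjusted p = 0.000111 with an estimated correlation). Antigen presentation was at 0.14 (adjusted p = 0.00647 with an estimated correlation) and 0.19 (adjusted p = 0.000246 with an estimated correlation). Microglia genes had medians of 0.34 in unimpaired (adjusted p = 0.0586 with an estimated correlation, 1.43e-10 without 5T-AI replicate 4) and 0.39 in impaired rats (adjusted p = 0.0104 with an estimated correlation), and lysosome genes 0.11 (adjusted p = 0.198 with an estimated correlation, 3.04e-06 without that array) and 0.22 (adjusted p = 0.0263 with an estimated correlation). In impaired rats the medians without that array were 0.21 for microglia, 0.57 for complement, 0.09 for antigen presentation and 0.11 for lysosome genes. For unimpaired rats 142 probe sets passed, 116 higher and 26 lower, and for impaired rats 210, 180 higher and 30 lower, with 197 and 298 when scan day was a block. These numbers became 222 and 128 without 5T-AI replicate 4, and with fluidics module as a term 36 and 27. The unequal numbers do not show a difference between the groups, which is tested directly below.

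On day 21 unimpaired rats (n = 10) had higher RT1-Da (2.22 ± 0.19, adjusted p = 1.35e-14), C3 (1.14 ± 0.12), Hspb1 (1.60 ± 0.24) and Gpd1 (2.12 ± 0.42), and lower Sema3c (-0.63 ± 0.10) and Tril (-0.32 ± 0.06), each in 10 of 10 arrays. The Gpd1 value is that of the dimmer of its 2 probe sets, with a young mean of log2 5.21. The brighter one passed as well, with means of log2 10.10 in unimpaired and 9.48 in young rats. Klf9, a transcription factor induced by glucocorticoids, rose 2.15-fold (adjusted p = 0.0269, 10 of 10 arrays) in 1 of its 2 probe sets and had the opposite sign in the other. Impaired rats (n = 9) had higher RT1-Da (2.32 ± 0.20, adjusted p = 5.37e-15), Hspb1 (2.06 ± 0.25), Cryab (0.83 ± 0.10), Qdpr (0.38 ± 0.05), Gfap (0.31 ± 0.06) and Mt2A, a metal-binding protein (0.59 ± 0.12), and lower Glra2 (-1.37 ± 0.30), each in 9 of 9 arrays. Complement had medians of 0.65 in unimpaired (adjusted p = 0.00134 with an estimated correlation) and 0.63 in impaired rats (adjusted p = 0.00053 with an estimated correlation), with 5 and 5 of 7 genes risen over all. Antigen presentation was at 0.17 (adjusted p = 0.000262 with an estimated correlation) and 0.15 (adjusted p = 0.00053 with an estimated correlation), and microglia genes at 0.42 (adjusted p = 0.0288 with an estimated correlation) and 0.37 (adjusted p = 0.031 with an estimated correlation). With scan day as a block the microglia value in impaired rats was 0.0623. Astrocyte genes had medians of 0.09 in unimpaired (adjusted p = 0.0634 with an estimated correlation) and 0.14 in impaired rats (4 of 28 risen over all and 10 adjusted over the list alone, adjusted p = 0.0058 with an estimated correlation), and myelin genes 0.14 in impaired rats (adjusted p = 2.26e-11, but adjusted p = 0.119 with an estimated correlation). In unimpaired rats 155 probe sets passed, 117 higher and 38 lower, and in impaired rats 182, 137 higher and 45 lower, with 460 and 272 when scan day was a block. Leaving out 5T-AI replicate 4 gave 316 and 293, and fluidics module as a term 29 and 95. With the actin ratio as a covariate 78 passed in unimpaired rats, and with the Gapdh ratio 90.

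The comparison the study was built around set impaired against unimpaired aged rats of the same age, day and training. On day 5 the immediate early genes, whose products alter synapses after neuronal activity, were lower as a list in impaired rats, but largely against the unimpaired rats of 1 code letter. The list had a median of -0.17, with 8 of 30 members above 0 and 9 fallen adjusted over the list alone and 0 over all probe sets (adjusted p = 7.23e-09, and adjusted p = 0.0143 with an estimated correlation). Arc, which acts at dendrites in memory storage, was at -0.54 ± 0.12 (adjusted p = 0.149, lower in 10 of 10 arrays), the nuclear receptor Nr4a1 at -0.37 ± 0.09 (adjusted p = 0.366) and the phosphatase Dusp1 at -0.64 ± 0.16 (adjusted p = 0.456). Egr1 was at -0.24 ± 0.08 and Fos at -0.74 ± 0.27 (both adjusted p = 0.985, lower in 9 of 10 arrays), and Homer1 at -0.44 ± 0.32, with 2 of its 5 probe sets of opposite sign. One of these, named for Homer1 in the comparisons with young rats, was at 0.15. None of these passed alone. The list's median was -0.17 with scan day as a block (adjusted p = 0.0386 with an estimated correlation), and within the 3 lots -0.13, -0.21 and -0.08. It was -0.16 without 5T-AI replicate 4, with an adjusted p of 7.98e-07 and of 0.0696 with an estimated correlation. With fluidics module as a term it was -0.07 (adjusted p = 0.0261), where module 1 held 7 impaired and 1 unimpaired array. With the letter of the animal code as a term it was -0.13 (adjusted p = 0.00026, but 0.243 with an estimated correlation). The 5 unimpaired rats of letter L were above the other 5 by 0.19 ± 0.05 for the list's mean, 0.69 ± 0.10 for Arc and 0.30 ± 0.07 for Egr1. Against those other 5 impaired rats were at -0.08 ± 0.04, -0.20 ± 0.17 and -0.09 ± 0.10. These parts were chosen after the values were seen.

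**Figure D4:**
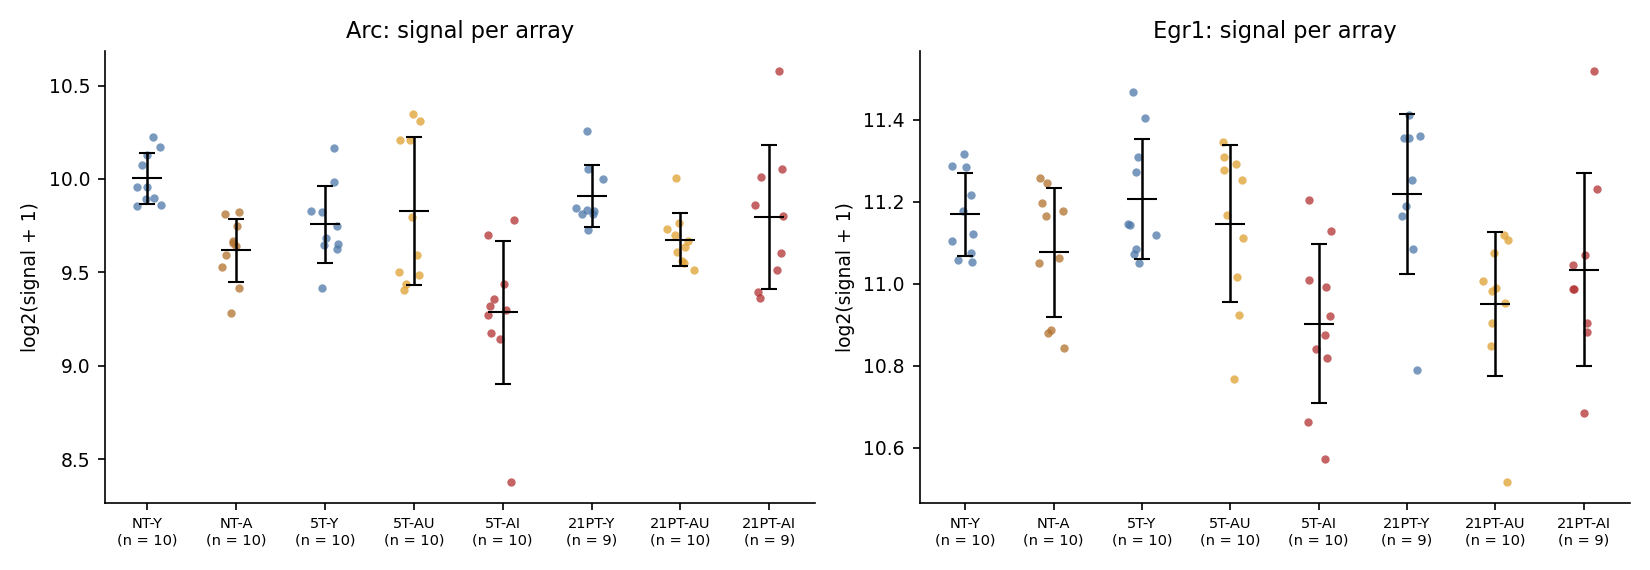
Log2 signal of the immediate early genes Arc (left) and Egr1 (right) in the 8 groups, 1 point per array, with bars for the mean and SD. Arc was at 9.83 ± 0.40 in unimpaired and 9.29 ± 0.38 in impaired rats on day 5.

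Most other list calls in this comparison ended or changed sign without 1 array, 5T-AI replicate 4. Microglia genes had a median of 0.15 in impaired rats (adjusted p = 0.000749, but adjusted p = 0.602 with an estimated correlation), with shifts of -0.03, 0.71 and -0.12 within the lots. Their median was -0.10 without 5T-AI replicate 4 (adjusted p = 0.0167, and 0.399 with an estimated correlation). Lysosome genes went from 0.08 (adjusted p = 0.591 with an estimated correlation) to -0.03 without that array and matrix genes from 0.08 (adjusted p = 0.641 with an estimated correlation) to -0.06. The preset calls for antigen presentation (0.09, adjusted p = 0.591 with an estimated correlation), interneuron (-0.07, adjusted p = 0.591 with an estimated correlation), synaptic vesicle (-0.07, adjusted p = 0.591 with an estimated correlation) and potassium and sodium channel genes (-0.07, adjusted p = 0.591 with an estimated correlation) ended without it. Glucocorticoid-responsive genes were at -0.08 (adjusted p = 0.011, but adjusted p = 0.591 with an estimated correlation), among them Nfkbia (-0.63 ± 0.20) and Ddit4 (-0.39 ± 0.14). Mbp (-0.04 ± 0.14), Mobp (-0.04 ± 0.08, 1 of 3 probe sets of opposite sign), Gfap (-0.01 ± 0.06), C3 (0.04 ± 0.12) and Slc2a1 (0.02 ± 0.08) were fixed for this comparison in advance and did not pass. Of 10371 probe sets 0 passed in limma, 475 had an unadjusted p under 0.05, and the smallest adjusted p was 0.149. Chance alone gives about 519 probe sets with such an unadjusted p, and this number applies to the comparisons below as well. With scan day as a block 0 passed as well.

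On day 21 the oligodendrocyte and myelin genes were higher in impaired rats (n = 9) than in unimpaired ones (n = 10). Of 31 members 30 were above 0, the median was 0.12 (adjusted p = 8.52e-10, but adjusted p = 0.623 with an estimated correlation), and 0 rose over all probe sets or adjusted over the list alone. Mobp, a protein of compact myelin, was at 0.21 ± 0.07 (8 of 9 arrays, 1 of its 3 probe sets of opposite sign), the myelin surface protein Mog at 0.17 ± 0.07, Mbp at 0.12 ± 0.07 and Gfap at 0.12 ± 0.06. The list's median was 0.12 with scan day as a block and 0.13 with fluidics module as a term. Ribosomal protein genes had a median of 0.05 (adjusted p = 6.88e-05, but adjusted p = 0.753 with an estimated correlation, and 0.389 with quantile normalization). Arc (0.12 ± 0.12), Egr1 (0.08 ± 0.08) and Fos (0.11 ± 0.27) did not pass (all adjusted p = 0.997). Kif1c, a motor protein (0.32 ± 0.08), and Penk, a precursor of opioid peptides (-0.33 ± 0.09), had the smallest p of single genes (both adjusted p = 0.985). In limma 0 probe sets passed, 477 had an unadjusted p under 0.05, and 0 passed with scan day as a block.

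Over both days together 0 probe sets passed in limma and 608 had an unadjusted p under 0.05. The smallest p were those of the calcium channel gene Cacna1a (-0.50 ± 0.12, 18 of 19 arrays, 1 of its 2 probe sets of opposite sign) and the serotonin receptor gene Htr7 (-0.25 ± 0.06), both at an adjusted p of 0.484. Myelin genes had a median of 0.08 (adjusted p = 8.90e-07, but adjusted p = 0.491 with an estimated correlation) and immediate early genes of -0.05 (adjusted p = 0.000495, but adjusted p = 0.491 with an estimated correlation). Of 85 probe sets with an unadjusted p under 0.01 on day 5, 51 (60%) had the same sign on day 21, and of 91 chosen on day 21, 49 (53.8%) had it on day 5, with 0 in both sets. The test of whether the difference changed between days passed for 0 probe sets in limma (347 at an unadjusted p under 0.05), with Arc at -0.67 ± 0.17 (adjusted p = 0.999). Immediate early genes as a list had a median of -0.20 in that test (adjusted p = 1.94e-05, but adjusted p = 0.159 with an estimated correlation), and glucocorticoid-responsive genes of -0.17 (adjusted p = 0.000769, but adjusted p = 0.288 with an estimated correlation).

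Training was compared with no training within each age, to ask what accompanied maze training. Learning was not separated from swimming or from the time of sampling in this comparison. In young rats on day 5 (n = 10 and 10) Gpd1 rose by 0.90 ± 0.16 (adjusted p = 0.00084, with its other probe set also higher and past the threshold), the sulfotransferase Sult1a1 by 0.52 ± 0.10, the clock genes Dbp by 0.45 ± 0.09 and Per2 by 0.36 ± 0.08 (adjusted p = 0.0324), and Homer1 by 0.59 ± 0.12 in 1 of 5 probe sets, with another of opposite sign. Ntng1, which guides axons, fell (-0.46 ± 0.08, adjusted p = 0.00078), and each of these was seen in 10 of 10 arrays. Immediate early genes had a median of -0.04 (adjusted p = 0.00157, but adjusted p = 0.316 with an estimated correlation), with 5 fallen adjusted over the list alone and 0 over all. Heat shock genes (0.04, adjusted p = 0.316 with an estimated correlation) and genes of cholesterol synthesis (-0.06, adjusted p = 0.316 with an estimated correlation) passed with the preset correlation alone. In all, 7 probe sets passed, 6 higher and 1 lower, 10 with scan day as a block, and 0 with fluidics module as a term.

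In aged rats on day 5 (n = 20 and 10) trained animals had higher Ptp4a3, a phosphatase (0.59 ± 0.09, adjusted p = 5.64e-05), Gjb6, a gap junction protein of astrocytes (0.49 ± 0.08), Per2 (0.41 ± 0.07, adjusted p = 0.000219), Gpd1 (0.79 ± 0.14) and Sult1a1 (0.48 ± 0.09), each in 20 of 20 arrays. The fat-splitting enzyme Pnpla2 (0.30 ± 0.06), Slc2a1 (0.32 ± 0.07, 19 of 20 arrays) and the chaperone partner Bag3 (0.29 ± 0.06) rose as well, while Ntng1 (-0.37 ± 0.07) and the lipoprotein lipase Lpl (-0.33 ± 0.08) fell. Of the glucocorticoid-responsive genes 2 of 22 rose over all and 4 adjusted over the list alone (median 0.17, adjusted p = 2.90e-07, but adjusted p = 0.0611 with an estimated correlation). The preset test passed for 11 lists, among them also complement (0.24, adjusted p = 0.477 with an estimated correlation) and, lower, genes of oxidative phosphorylation (-0.04, adjusted p = 0.725 with an estimated correlation, and a preset adjusted p of 0.105 without 5T-AI replicate 4). In all, 16 probe sets passed, 12 higher and 4 lower, and 29 with scan day as a block. With fluidics module as a term 3 passed, Per2, Gjb6 and Ptp4a3. Whether the difference between trained and untrained rats changed with age was tested directly: 0 probe sets passed in limma and 386 had an unadjusted p under 0.05.

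**Figure D5:**
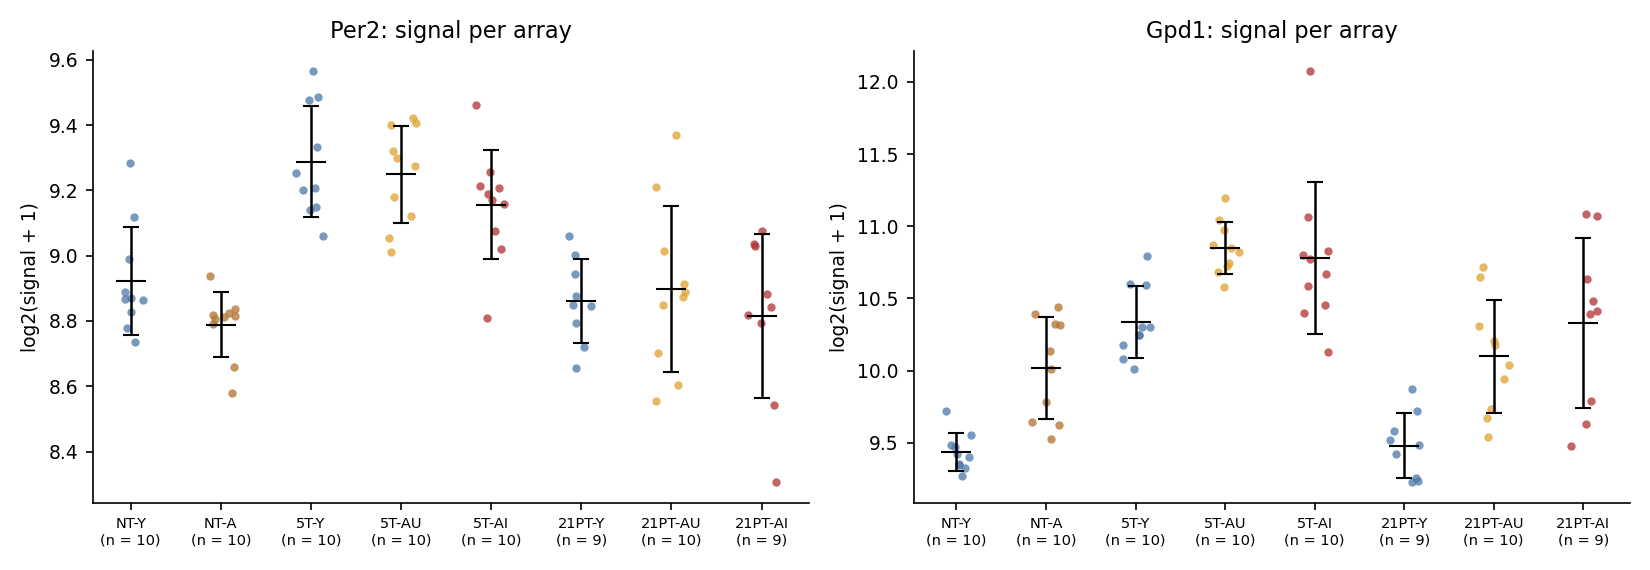
Log2 signal of Per2 (left) and Gpd1 (right) in the 8 groups, 1 point per array, with bars for the mean and SD. Per2 had means of 9.16 to 9.29 in the day 5 groups and of 8.79 to 8.92 in the other groups.

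By day 21 after training 0 probe sets differed from untrained rats in either age (limma, with 253 at an unadjusted p under 0.05 in young and 575 in aged rats, and 0 in both with scan day as a block). In young rats (n = 9 and 10) Coq8a, a mitochondrial kinase, had the smallest p (0.32 ± 0.08, adjusted p = 0.812), and immediate early (-0.07, adjusted p = 0.736 with an estimated correlation) and heat shock genes (-0.04, adjusted p = 0.736 with an estimated correlation) passed with the preset correlation alone. In aged rats (n = 19 and 10) Iars1, which loads isoleucine onto its tRNA (0.46 ± 0.11), and Itih3 (0.28 ± 0.07, 19 of 19 arrays) both had an adjusted p of 0.229, and Slc2a1 was at 0.27 ± 0.07 (adjusted p = 0.283). Vessel genes had a median of 0.11 in these rats, with 0 of 18 risen over all and 2 adjusted over the list alone (adjusted p = 1.13e-06, but adjusted p = 0.223 with an estimated correlation). In aged rats Ptpn18 passed without 5T-AI replicate 4 (0.43, adjusted p = 0.0271), named here after its value was seen.

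Day 21 was compared with day 5 over all trained rats (n = 28 and 30), to ask what faded or grew after training ended. Lower on day 21 were Per2 (-0.37 ± 0.05, adjusted p = 1.44e-07, 27 of 28 arrays), Gpd1 (-0.68 ± 0.09, 25 of 28 arrays, 1 of 2 probe sets), Homer1 (-0.50 ± 0.07, 1 of 5 probe sets, another of opposite sign), Sult1a1 (-0.38 ± 0.06) and Gjb6 (-0.32 ± 0.05, adjusted p = 0.000202). Fkbp5, a partner of the glucocorticoid receptor, fell (-0.23 ± 0.05), as did Bag3 (-0.21 ± 0.04). Ntng1 (0.34 ± 0.05, 26 of 28 arrays), the adenylate cyclase Adcy8 (0.47 ± 0.07, adjusted p = 2.06e-05) and Insig1, a sterol sensor (0.18 ± 0.04, 25 of 28 arrays), rose. Genes of cholesterol synthesis were higher on day 21 (median 0.09, 19 of 21 above 0, 1 risen over all and 3 adjusted over the list alone, adjusted p = 3.01e-08, adjusted p = 0.0103 with an estimated correlation), by 0.06, 0.09 and 0.08 within the lots. Glucocorticoid-responsive genes were lower (median -0.07, 2 of 22 above 0, 2 fallen over all and 5 adjusted over the list alone, adjusted p = 6.00e-07, adjusted p = 0.0462 with an estimated correlation), with -0.10, -0.09 and -0.05 within the lots. With scan day as a block the medians were 0.09 and -0.08. Without 5T-AI replicate 4 the glucocorticoid value with an estimated correlation was 0.0738. In all, 26 probe sets passed, 4 higher and 22 lower, and 45 with scan day as a block.

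Maze measures of each animal were set against expression among the 39 trained aged rats, as a graded form of the impaired and unimpaired groups. With day in the model 0 probe sets passed in limma for any of 8 measures. At an unadjusted p under 0.05 there were 426 for escape latency and 964 for the time to enter the platform site in the probe trial. Chance gives about 519, and these counts were not set against random divisions. With group added to the model Sertad1 passed for latency (-0.80 per SD, adjusted p = 0.0279), Lenep (-0.51, adjusted p = 0.00462) and Gria3, an AMPA receptor subunit (-0.16, adjusted p = 0.0161), for probe distance, and Ppil4 for quadrant share (0.18, adjusted p = 0.0042). These 4 genes were named after their values were seen. Their p were adjusted within each fit and not over the 8 measures. The outlying array 5T-AI replicate 4 had the lowest quadrant share of these rats (7.7%) and the highest probe distance of its group (60.4 cm). The fits of the maze measures were not repeated without it. Latency formed separate clusters in impaired and unimpaired rats, so that the fits with day alone largely restated the comparison of the groups.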

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

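The tests of choroid plexus, of blood, of the letter of the animal code, of hippocampal subfields and of fluidics module for the immediate early genes were chosen only after the results were seen, as were the random divisions for probe sets, all divisions within scan days and the swaps within days for the myelin genes.

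In 13 of 98 groups of values 1 sample lay far from the others of its group, where chance gives about 1 in 20. The number given is the gap to the nearest sample over the range of the group. The array 5T-AI replicate 4 accounted for 5 of them: highest median signal (0.621; 269 against 237.3 to 249.3), lowest mean correlation with the other arrays (0.880), highest C3 (0.656), lowest Arc (0.545) and highest Gpd1 (0.518). Low mean correlation also marked NT-Y replicate 3 (0.643) and 21PT-Y replicate 6 (0.534). The actin ratio was highest in 5T-Y replicate 3 (0.526), RT1-Da in 21PT-AI replicate 5 (0.651) and Arc in 21PT-AU replicate 8 (0.485), and Egr1 lowest in 21PT-AU replicate 10 (0.552). Escape latency was long in the young rats 5T-Y replicate 10 (0.503; 24.2 s) and 21PT-Y replicate 2 (0.519; 19.9 s).

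Gene lists whose difference between impaired and unimpaired rats changed from day 5 to day 21, by a direct test with the preset correlation, were immediate early genes (adjusted p = 1.94e-05), glucocorticoid-responsive genes (adjusted p = 0.000769), myelin genes (adjusted p = 0.00102), microglia (adjusted p = 0.00897), antigen presentation (adjusted p = 0.0091), fatty acid oxidation (adjusted p = 0.0232) and matrix genes (adjusted p = 0.0418). With an estimated correlation the adjusted p were 0.159, 0.288, 0.707, 0.707, 0.707, 0.288 and 0.707 in that order. Without 5T-AI replicate 4 the adjusted p was 0.203 for fatty acid oxidation and 0.41 for antigen presentation, and microglia (0.131) and matrix genes (0.623) changed sign. The difference between trained and untrained rats changed with age for complement (adjusted p = 0.0433) and calcium handling (adjusted p = 0.0433), with 0.909 for both with an estimated correlation and 0.298 for both without 5T-AI replicate 4. With scan day as a block neither of these 2 lists passed. All 9 of these lists failed the stricter test.

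Immune genes were higher in aged rats of all 3 cohorts: 24 of 48 members of the complement, microglia and antigen presentation lists rose in at least 1. The values below rest on these members, which were chosen by their calls for age in the same arrays. Differences within modules set aged against young arrays across training and day, and not within a cohort. The tables argue against fluidics module as the cause, since within modules the difference was 0.99 ± 0.19, 0.85 ± 0.07, 0.83 ± 0.04 and 1.11 ± 0.12 (the last with 1 young array) and at its lowest 94.8% of that over all arrays (0.88 ± 0.06; 49 aged, 29 young). They argue against RNA quality, as the 3' over 5' ratios as covariates left at least 98.6% of it, and against choroid plexus tissue, whose 9 genes had medians of 0.00, -0.11 and -0.05 against 0.53, 0.70 and 0.64 for the called members (-0.65% at the highest; the brightest, Enpp2, was at 0.23, 0.11 and 0.02, and is also in the myelin list). Blood in the tissue is argued against as the whole cause, although Hbb rose by 0.90 ± 0.21, 0.89 ± 0.18 and 0.96 ± 0.19. With Hbb as a covariate at least 83.4% of the immune difference was left (0.67 ± 0.12, 0.79 ± 0.11 and 0.72 ± 0.11), while the red cell gene Alas2 went from 0.73, 0.61 and 0.94 to -0.15, -0.26 and 0.01. A 3rd red cell gene, Slc4a1, was at -0.18, -0.24 and 0.03 and did not pass. A part played by blood stays open, as does the source of the rise of Hbb. The letter of the animal code is argued against in untrained rats and on day 21, where as a term it left at least 103% and within letters the difference was 0.85 ± 0.05 and 0.94 ± 0.07. On day 5 it cannot be told apart as the cause. As a term it left 87.4%, but within letters, of which K, M and O held both ages, the difference was 0.57 ± 0.20 against 0.92. The wide standard error within letters leaves this undecided. Age, which the design names, was compared in 3 cohorts that share no array. Over all genes 56 probe sets passed in each with the same sign and 0 with opposite signs. Whether age itself or something that goes along with it gives the immune rise was not tested further.

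Immediate early genes were lower in impaired rats on day 5 (mean -0.17 ± 0.04). The tables argue against 1 outlying array (-0.16 ± 0.05 without it) as the whole cause, although the call with an estimated correlation ended there (adjusted p = 0.0696). They argue in the same way against a shift of hippocampal subfields as the whole cause. The larger subfield median was 6.7% of that of the list: 0.01 over 7 dentate genes (SD between genes 0.12, with Dsp at -0.29) and -0.01 over 15 CA genes (SD 0.07). Fluidics module and group cannot be told apart here, since 7 impaired arrays but 1 unimpaired shared module 1, and with module as a term the mean was -0.10 ± 0.06. The letter of the animal code cannot be told apart either. As a term it left -0.14 ± 0.05 (-0.1383), but the 5 unimpaired rats of letter L, a letter with 0 impaired rats, stood 0.19 ± 0.05 above the other 5. Within letters the mean was -0.03 ± 0.06. The list's camera p was 2.33e-10, as small in 1 of 100 divisions, the real one included (next 4.89e-09), and in 2 of 100 within scan days. Impairment itself, as named by the design, stays open and untested.

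Myelin genes were higher in impaired rats on day 21 (mean 0.11 ± 0.06, 7 of 9 rats above the unimpaired mean). Spread between single animals cannot be told apart from this: the exact permutation p was 0.0981 over 92378 divisions, but 0.0391 for swaps within the 8 scan days that held both groups (0.14 ± 0.05 between the arrays of a day). As small a camera p came from 9 of 100 random divisions and from 2 of 100 within scan days. More white matter in the dissection cannot be told apart from it, as the difference followed how closely a member tracks the list only weakly (r = 0.205 ± 0.17 over 31 members). The tables argue against scan day as the cause, since with it as a block the mean was 0.11 ± 0.06 and the part taken away 0.00 ± 0.02. The letter of the animal code cannot be told apart: as a term it left 0.13 ± 0.06 (0.1344), and within letters 0.09 ± 0.07. Impairment stays open and untested.

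Chance can be excluded for the counts of probe sets in the comparisons with age. Out of 100 divisions of the same arrays, the real one included, 1 gave as many as the real count (highest other in parentheses) in untrained rats, 81 (28), on day 5, 259 (1), on day 21, 295 (10), and in unimpaired and impaired against young rats on day 5, 142 (2) and 210 (13), and on day 21, 155 (16) and 182 (5). It can be excluded in the same way for training in aged rats on day 5, 1 with 16 (3), and for day 21 against day 5, 1 with 26 (2). For training in young rats on day 5, 2 divisions gave as many as the real 7. The highest other had 119, so that these divisions do not exclude chance there. It cannot be excluded for probe sets at an unadjusted p under 0.05 in impaired against unimpaired rats on day 5, 76 divisions with 475 (1316), day 21, 57 with 477 (1306), and both days, 47 with 608 (1689). Nor can it be for training by day 21 in young, 81 with 253 (1882), and aged rats, 37 with 575 (1341), for the change of impairment with day, 87 with 347 (1585), for that of training with age, 52 with 386 (2033), or for the 60% of probe sets of the same sign on both days, 24 (78.1). Divisions with several times the real number point to a structure of the samples that crosses the groups. Scan day and chip lot carry one, with 5132 and 4488 of 10371 probe sets that passed for them in limma, and these divisions were not restricted to days or lots. In the same kind of fit 1909 probe sets passed for the letter of the animal code and 0 for fluidics module. With arrays moved only within scan days the other verdicts on numbers of probe sets stayed. As many came from 1 of 100 divisions for every comparison with passing probe sets, also for training in young rats on day 5 (highest other 0). For impaired against unimpaired rats as many came from 38 on day 5 (highest other 814), 29 on day 21 (936) and 11 over both days (1238). For training by day 21 these were 68 in young (1011) and 8 in aged rats (789), and for the changes of impairment with day and of training with age 70 (1065) and 23 (761). The share of the same sign was not tested within days.

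For the number of lists called with the preset correlation, chance can be excluded for age on day 21, 1 division with 13 (11), for unimpaired against young rats on day 5, 4 with 10 (10), and for impaired against young rats on day 21, 1 with 13 (12). It cannot be excluded for age in untrained rats, 8 with 8 (10), and on day 5, 26 with 14 (20), for impaired against young rats on day 5, 19 with 17 (22), or unimpaired against young rats on day 21, 12 with 9 (10). The same holds for impaired against unimpaired rats on day 5, 89 with 9 (24), day 21, 71 with 2 (11), and both days, 74 with 7 (17), and for training in young, 5 with 6 (7), and aged rats on day 5, 37 with 11 (21), and on day 21, 57 with 2 (11) and 50 with 3 (9). It also holds for day 21 against day 5, 76 with 6 (17), and the changes of impairment with day, 89 with 7 (19), and of training with age, 88 with 2 (20). Within scan days 2 of these verdicts changed: 6 divisions gave as many lists for unimpaired against young rats on day 5 (highest other 12), and 3 did for training in young rats on day 5 (7).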

How the results depend on the processing

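Fluidics module, the actin ratio, the 2 arrays left out and, for gene lists, scan day and animal letter were chosen only after the data were seen. Quantile normalization, a pseudocount of 32 and no filter left every count of probe sets within 1.5 times the reported one, and impaired against unimpaired rats, both interactions and young rats on day 21 had 0 in limma under every alternative (unadjusted counts are in the report). Over the 17 comparisons 139 list calls were made, 142 with the mean of a gene's probe sets, 147 with quantile normalization, 136 with scan day as a block, 110 with module, 107 without 5T-AI replicate 4, 160 with the animal letter, 27 with an estimated correlation, 34 with the array left out as well and 22 with the letter as well. Why counts moved was not tested. A term nearly following the groups leaves less to estimate from: module raised the median standard error in untrained rats from 0.0824 to 0.116. Fewer arrays in the fit leave less as well, but several counts rose when arrays were left out.

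With scan day as a block age on day 21 gave 487, unimpaired against young rats on day 21 460, training in aged rats on day 5 29 and day 21 against day 5 45. With the animal letter age on day 5 gave 145, unimpaired against young rats on day 5 44, training in aged rats on day 5 9, day 21 against day 5 42, and the share of the same sign across days 72.5% and 71.3%. With the letter and an estimated correlation 9 described lists lost their call (adjusted p): microglia (0.0658) and lysosome genes (0.121) with age on day 5, antigen presentation (0.141) and glucocorticoid-responsive genes (0.197) in unimpaired and lysosome genes (0.0512) in impaired against young rats on day 5, microglia in both on day 21 (0.0769 and 0.0623), immediate early genes in impaired against unimpaired rats on day 5 (0.243) and glucocorticoid-responsive genes in day 21 against day 5 (0.261). With only the arrays of the contrast untrained rats gave 149, age on day 5 169, and unimpaired and impaired against young rats on day 5 221 and 72. With the Gapdh ratio unimpaired against young rats on day 21 gave 90. With the actin ratio age on day 21 gave 164, unimpaired against young rats on day 21 78, training in aged rats 33 on day 5 and 1 on day 21 (Itih3, 0.33, adjusted p = 0.0383). With module the counts were 27, 54 and 116 for age in untrained, day 5 and day 21 rats, 15 for all 3 cohorts, 36 and 27 for unimpaired and impaired against young rats on day 5, 29 and 95 on day 21, 0 and 3 for training in young and aged rats on day 5, and the share selected on day 21 was 39.4%. With group as a covariate of the maze measures latency gave 1, probe distance 2 and quadrant share 1.

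Without 5T-AI replicate 4 or 21PT-Y replicate 6 the counts ran from 85 to 170 in untrained rats, 142 to 222 and 128 to 216 for unimpaired and impaired against young rats on day 5, 113 to 316 and 166 to 293 on day 21, 0 to 1 for training in aged rats on day 21 and 52 to 106 for all 3 cohorts. Without 5T-AI replicate 4 these lists reversed (adjusted p, then with an estimated correlation): in impaired against unimpaired rats on day 5 microglia (0.0167, 0.399), lysosome (0.277, 0.756), matrix (0.277, 0.931) and synaptic vesicle genes (0.979, 0.981), and in the change of impairment with day microglia (0.131, 0.586) and matrix genes (0.623, 0.804). Among genes that did not pass in impaired against unimpaired rats on day 5, Mobp went to 0.0536 with module, and over the 2 arrays left out C3 ran from -0.107 to 0.0382 and Slc2a1 from -0.0274 to 0.0238.

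Replicate numbers do not pair the animals by a stated rule. As a block they gave 501 for age on day 21, 341 for unimpaired against young rats on day 21, 27 for training in aged rats on day 5 and 43 for day 21 against day 5. Arrays with the same number correlated at a mean of 0.138 (-0.248 to 0.482), and 29 of 78 correlated best with their own number. The number was the rank of the scan day within the group in 53 of 78 arrays. For scan day itself the mean was 0.183 and 43 of 78 arrays correlated best with their own day, and for chip lot 0.116 and 62 of 78.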

Other observations

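The tests of time of day and steroid response below were run on a pattern noticed in these data. Genes higher on day 5 than on day 21 included the clock gene Per2 and glucocorticoid-responsive genes. The animals may have been sampled at another time of day: of the 3 genes of the opposite clock phase 2 were lower on day 5 at an unadjusted p under 0.05 in limma, Bmal1 (-0.13, p = 0.021) and Nfil3 (-0.18, p = 0.0197), while Clock was at -0.03 (p = 0.649), and none of them passed after adjustment. Of genes in phase with Per2, Bhlhe41 passed as higher on day 5 (0.17, adjusted p = 0.00494). Dbp (0.17, adjusted p = 0.278), Nr1d2 (0.09, adjusted p = 0.611), Per1 (0.00), Nr1d1 (-0.03) and Tef (-0.23) did not pass. A steroid response to swimming could give the pattern as well, but the test run for it cannot tell: the glucocorticoid-responsive list without Per1 (camera p of 0.00201 with an estimated correlation, 19 of 21 members lower on day 21) holds the same genes as the pattern. Both explanations remain open, and neither excludes the other.

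Of the 31 lists tested, 6 passed in none of the 17 comparisons: choroid plexus, CA pyramidal cells, proteasome, thalamus and striatum, tricarboxylic acid cycle, and neurogenesis and cell cycle.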
